A study of Homo sapiens with 11 samples.

How the data were processed

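The series measured RNA in SUM159 cells, a human triple-negative breast cancer line, carrying a non-targeting control hairpin (NTC) or 1 of a pair of SMARCA4 knockdown derivatives (KD1 and KD2). Per the labels' protocols, spheroids (3D) were grown for 8 to 10 days on ultra-low attachment plates, and monolayers (2D) for 2 days on regular plates. There were 3 spheroid libraries each of NTC, KD1 and KD2, and 1 monolayer library each of NTC and KD1. Total RNA was depleted of ribosomal RNA and made into Illumina libraries with the PrepX protocol on an Apollo instrument, per the labels' protocols. Ribosomal RNA depletion leaves RNA without poly(A) tails, such as snoRNA, in the library, so the share taken by such RNA sets how much is left for the other genes.

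Per the submitters' processing notes, STAR 2.7.8a, Partek and the hg38 build were used. The annotation release, the way reads were assigned to genes, the use of strand and the filter on low genes are not given in the sources used here. The authors deposited 1 table for the 9 spheroid libraries (26023 genes) and 1 for the 2 monolayer libraries (22958 genes and 2 lines that name no gene, 1 of which holds the number 0.996554984, equal to the Pearson correlation of the 2 columns). In both tables the deposited signal is CPM (counts scaled to a library total of 1e6) plus 1. Each column less 1 per gene sums to 1e6, and a gene without reads is listed at 1. The deposited CPM are therefore relative abundances within a library. A gene's CPM also falls when an abundant RNA class rises.

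The step between low values gave the depth of each library in reads assigned to genes. It was 26.2 and 30.8 M (1e6 reads) in 2D and 29.6 to 52.3 M in 3D. Between 74.5% and 81.4% of low values were whole multiples of that step within 1.1e-05 CPM, and the rest were counted as fractions of a read. Whole counts were therefore not recovered, and count-based tests, the first choice in the design, were not used. Instead the fallback written beside them was run. The limit that a count of 0 allows (3 reads) was 0.0574 to 0.101 CPM in 3D and 0.0973 to 0.115 CPM in 2D. Such floors, and the intervals given for single libraries, cover counting error only.

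For the spheroids, 1 was subtracted from each value and log2(CPM + 1) was analysed with limma 3.58.1 in R 4.3.3 (trend, not robust). Fold changes are on this scale, which understates the change of genes near or under 1 CPM. Genes with at least 1 CPM in at least 3 of the 9 libraries were kept (16090). A single model over NTC, KD1 and KD2 shared 1 estimate of the spread with 6 residual degrees of freedom and had no term for the replicate number. The contrasts were KD1 against NTC, KD2 against NTC and KD2 against KD1, all two-sided, with Benjamini-Hochberg adjusted p under 0.05 counted as a change. The labels number the replicates without saying whether they were separate cultures, so p-values measure the spread between these libraries, which may be technical.

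Gene lists (37, fixed before the data were examined) were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with SMARCA4 left out. Camera compares a list with all other genes, so its call is relative to the middle of the distribution. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way. Lists with fewer than 3 measured members were not tested. For each list the members past the threshold were counted over all genes and again adjusted over the list alone. Results are not given here for every list.

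Named genes were chosen by a rule written beforehand. It took SMARCA4, ARHGAP29 and RHOA always. It took the 12 largest rises and the 12 largest falls, by the smaller of both fold changes, among genes called the same way with both knockdowns, with all knockdown libraries on 1 side of all NTC libraries and at least 5 CPM in the highest group mean. It took the 8 largest called differences each way between KD2 and KD1 with non-overlapping libraries, the 8 largest ratios each way in 2D among genes with at least 10 CPM, and for each list the 4 members with the smallest adjusted p over KD1 and KD2 together (the larger of both p). Symbols of unnamed transcripts and of most small RNA families were left out. Coordinates are those of the deposited tables, in hg38. At the 12311 spheroid genes with the same identifier and version in GENCODE 29, the start was the same and the deposited stop lay 1 base past the end, so 1 was subtracted from it.

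With 1 monolayer library per group there is no replicate check and no p-value in 2D. Genes with an absolute log2 ratio of at least 1, pseudocount 1, and at least 5 CPM in the higher library were counted. A list's median was placed among 10000 random lists of the same size matched on mean expression. Intervals of a ratio of 2 libraries are exact (Clopper-Pearson, 95%) on the reads inferred from the depth, and compare those libraries, not the conditions. The 2 tables were never tested together.

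The fit was tested on simulated data drawn from the genes' NTC means and the inferred depths. In the simulated KD1 comparison (15330 genes) it recovered 28.0% of genes changed 1.5-fold, 94.0% at 2-fold and 100% at 4-fold and 8-fold, with 13 false calls. In the simulated KD2 comparison (15293 genes) the shares were 20.4%, 88.0%, 100% and 100%, with 9 false calls. The spread in the simulation (squared coefficient of variation 0.0264) was a single value for all genes, a trimmed mean over well-covered genes of the libraries. Recovery may therefore be lower for real genes with a larger spread.

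Alternatives were a replicate block, fits of only the groups compared, quantile normalization, no filter, a filter at 5 CPM, limma without the trend, a test against a 1.5-fold change, pseudocounts of 0.1 and 5, each library left out in turn and, for 2D, other minimum levels and ratios. Scaling to the total of the protein-coding genes was chosen after seeing the data. Other steps ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots in matplotlib 3.10.9.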

Results

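RNA was compared between SUM159 cells with a non-targeting hairpin (NTC) and SUM159 cells with a knockdown of SMARCA4, which encodes the BRG1 ATPase of the SWI/SNF chromatin-remodelling complex. SUM159 is a triple-negative breast cancer line. The spheroid (3D) set held 3 NTC, 3 KD1 and 3 KD2 libraries of 29.6 to 52.3 M assigned reads, and the monolayer (2D) set 1 NTC library (26.2 M) and 1 KD1 library (30.8 M). Protein-coding genes took 82.1% to 85.8% of the reads in 3D and 65.5% (NTC) and 59.0% (KD1) in 2D. Small nucleolar RNA took 4.49% to 9.87% in 3D and 28.3% and 32.9% in 2D, where SNORD3A alone took 12.2% and 13.4%. In 3D the first principal component (36.7% of the variance) set the KD2 libraries apart from the rest, and the second (16.6%) set KD1 apart from NTC. Replicate 3 of KD2 stood furthest out, with 1.65% of its reads on MALAT1 against 0.902% to 1.14% in the other spheroid libraries.

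SMARCA4 RNA was lower in the KD2 spheroids than in NTC, and the difference between KD1 and NTC did not pass the threshold. SMARCA4 (ENSG00000127616, chromosome 19, 10960825 to 11079426) was at 16.3, 19.6 and 29.7 CPM in NTC replicates 1 to 3, at 10.6, 13.5 and 16.3 CPM in KD1 and at 9.26, 3.53 and 2.81 CPM in KD2. The means were 21.9 ± 6.94, 13.4 ± 2.84 and 5.2 ± 3.53 CPM (SD, n = 3 each). In limma the log2 fold change was -0.64 (SE 0.39, adjusted p = 0.4839) in KD1 and -1.98 (adjusted p = 0.0016) in KD2. The KD2 level was below that of KD1, by -1.34 (adjusted p = 0.0272). In 2D, SMARCA4 was at 5.84 CPM in NTC and 2.92 CPM in KD1, a log2 ratio of -0.80, with an interval of -1.39 to -0.62 for the ratio of the plain CPM, which rests on about 153 and 90 reads. SMARCA2, which encodes the alternative ATPase of the complex and was picked out after its values were seen, was at 80.7 CPM in NTC, 70.4 CPM in KD1 and 39.6 CPM in KD2 (log2 fold change in KD2 -1.01, adjusted p = 2.17e-04).

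The series title links SMARCA4 to ARHGAP29, which encodes a GTPase-activating protein, and to RHOA, the small GTPase it switches off. ARHGAP29 (ENSG00000137962, chromosome 1, 94148988 to 94275068) fell with both knockdowns, from 246 ± 21.8 CPM in NTC to 126 ± 14.9 in KD1 and 35.2 ± 0.465 in KD2 (SD, n = 3 each). Its log2 fold change was -0.96 (SE 0.15, adjusted p = 7.47e-04) in KD1 and -2.76 (adjusted p = 8.87e-10) in KD2. KD2 lay below KD1 by -1.80 (adjusted p = 3.41e-07). The KD1 fall did not pass a test against a 1.5-fold change (adjusted p = 0.4685, range over the alternatives 7.11e-05 to 0.4685). RHOA RNA (ENSG00000067560, chromosome 3, 49359145 to 49412998) was at 700 ± 74.6, 672 ± 38.8 and 853 ± 66.5 CPM, with log2 fold changes of -0.06 (adjusted p = 0.8944) in KD1 and 0.29 (adjusted p = 0.1177) in KD2, and the KD1 value changed sign to 0.04 with quantile normalization. In 2D, ARHGAP29 was at 142 CPM in NTC and 77.1 in KD1 (log2 ratio -0.88, interval -0.96 to -0.81), and RHOA at 865 and 699 CPM (-0.31, interval -0.33 to -0.28), beside a median log2 ratio of -0.13 over all genes with at least 5 CPM. RHOA overlaps TCTA, and SMARCA4 and ARHGAP29 overlap unnamed transcripts, on the opposite strand, and the use of strand in counting is not stated, so some of their reads may be misassigned.

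**Figure D1:**
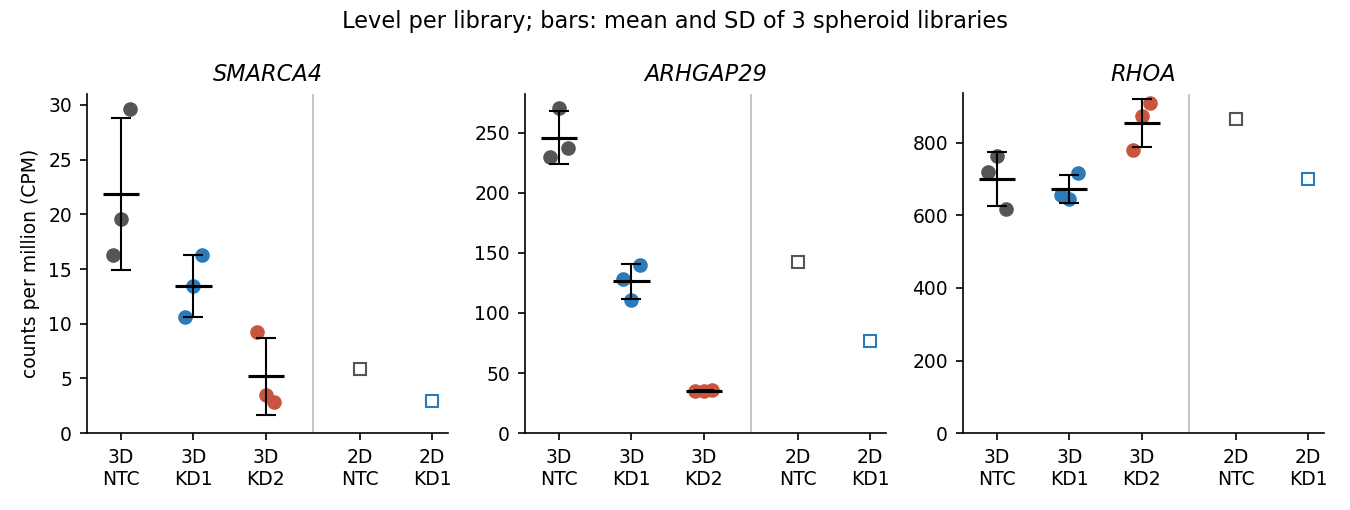
Levels of SMARCA4, ARHGAP29 and RHOA in CPM in each library, with 3D groups as filled points (bar and whisker: mean and SD of 3 libraries) and the single 2D libraries as open squares. ARHGAP29 fell from 246 to 126 and 35.2 CPM in 3D, while the lowest NTC and highest KD1 library of SMARCA4 were both at 16.3 CPM.

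KD1 spheroids had lower RNA of some matrix, mesenchymal and mitochondrially encoded genes than NTC, and higher RNA of some epithelial genes. As lists these were called at a preset correlation only, with adjusted p = 0.0869, 0.0887, 0.1181 and 0.0869 with an estimated correlation. FN1, which encodes fibronectin, fell from 1306 CPM to 376 (log2 fold change -1.79, adjusted p = 1.52e-06), and COL3A1, a fibrillar collagen gene, from 1143 to 359 CPM (-1.67, adjusted p = 3.58e-06). PLAT, which encodes tissue plasminogen activator, rose from 19.2 ± 2.83 to 200 ± 17.7 CPM (SD, n = 3 each; 3.32, SE 0.19, adjusted p = 3.84e-08). Of 16090 genes tested, 292 rose and 409 fell (2485 at an unadjusted p under 0.05), with a median fold of 2.30 among the rises and 0.345 among the falls. The 3 libraries of both groups did not overlap for 22.8% of genes, where chance gives 10.0%. The count of 701 genes became 395, 369 and 371 without NTC replicate 1, 2 or 3, 418 without KD1 replicate 2 and 1076 without KD2 replicate 3, which enters only through the shared spread and the filter. Tested against a 1.5-fold change it was 149.

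Camera called 7 of 36 lists in KD1, 3 up and 4 down, and none with an estimated correlation. In the collagens and matrix list 11 of 25 members fell and 0 rose (13 fell adjusted over the list alone; adjusted p = 5.00e-12, and adjusted p = 0.0869 with an estimated correlation). THBS1 (thrombospondin) was at 2658 CPM in NTC and 1210.3 in KD1. VCAN (the proteoglycan versican) was at 864 and 372, and COL4A1 at 285 and 121. Among mesenchymal genes 8 of 24 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 1.10e-04, and adjusted p = 0.0887 with an estimated correlation). TGFBI fell to 260 CPM from 637, PDGFRB, a growth factor receptor of mesenchymal cells, to 44.6 from 134, and POSTN (periostin) to 53.2 from 163. Of the mitochondrially encoded genes 7 of 15 fell and 0 rose (12 fell adjusted over the list alone; adjusted p = 1.77e-10, and adjusted p = 0.1181 with an estimated correlation). MT-CO3 was at 1656 CPM in NTC and 897 in KD1. Of the 24 genes on the epithelial list only 13 were measured. Among epithelial genes 4 of 13 rose and 0 fell (4 adjusted over the list alone; adjusted p = 2.87e-04, and adjusted p = 0.0869 with an estimated correlation). These were the tight-junction genes CLDN1 (70.5 to 165 CPM) and CLDN4 (1.85 to 14.9), the desmosomal DSP (47.6 to 84.6) and the keratin gene KRT18 (35.8 to 69.7), which overlaps KRT8 on the opposite strand.

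In the list of matrix proteases and inhibitors 3 of 20 rose in KD1 and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0090, and adjusted p = 0.2314 with an estimated correlation). Besides PLAT they were ADAM19 (8.81 to 25 CPM) and MMP1 (14.1 to 36.4), an interstitial collagenase. Of the G2 and mitosis genes 2 of 25 rose and 0 fell (7 adjusted over the list alone; adjusted p = 1.10e-04, and adjusted p = 0.3455 with an estimated correlation). They were the spindle checkpoint kinase gene BUB1 (log2 fold change 0.87) and the cyclin gene CCNB1 (0.55). Of the genes of fatty acid synthesis and desaturation 1 of 13 fell and 0 rose (2 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.5620 with an estimated correlation). It was ME1, which encodes the cytosolic malic enzyme, at 112 and 61.7 CPM. The fatty acid call ended with quantile normalization (adjusted p = 0.0694) and without NTC replicate 3, KD1 replicate 2 or KD1 replicate 3 (adjusted p = 0.0717, 0.0532 and 0.0743).

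KD2 spheroids lost most of the RNA of many matrix genes. VCAN fell from 864 ± 89.9 CPM in NTC to 16.9 ± 1.45 (SD, n = 3 each; log2 fold change -5.59, adjusted p = 2.12e-13), COL5A1 from 150 ± 10.1 to 3.62 ± 0.840 (-5.04, adjusted p = 3.19e-11) and MMP2, a gelatinase gene, from 149 ± 6.49 to 4.08 ± 2.63 (-5.00, adjusted p = 8.55e-10). IL7R, a cytokine receptor gene, fell from 278 ± 11 to 7.52 ± 1.19 CPM (-5.04, adjusted p = 4.02e-12). CLDN1 rose from 70.5 to 575 CPM (3.03, adjusted p = 2.93e-10) and BIRC3, an inhibitor of apoptosis gene, from 80.3 to 501 CPM (2.63, adjusted p = 2.30e-09). Of the genes tested 1129 rose and 1836 fell (4786 at an unadjusted p under 0.05), with a median fold of 1.85 and 0.369, and libraries did not overlap for 34.1% of genes. Without KD2 replicate 3 the count was 2985 in place of 2965, and tested against a 1.5-fold change it was 882. The median log2 fold change of all genes was -0.10 and became 0.06 with quantile normalization, under which 1495 genes rose and 1571 fell, so changes of that size have no fixed direction.

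Camera called 12 of 36 lists in KD2, 4 up and 8 down. Those of the collagens and matrix, mesenchymal and epithelial lists held with an estimated correlation. In the collagens and matrix list 21 of 25 fell and 0 rose (23 and 1 adjusted over the list alone; adjusted p = 3.40e-26, and adjusted p = 0.0112 with an estimated correlation). COL3A1 was at 67.8 CPM, COL4A1 at 27.8 and THBS1 at 488. Of the mesenchymal genes 15 of 24 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 1.14e-14, and adjusted p = 0.0112 with an estimated correlation). FN1 was at 181 CPM, TGFBI at 75.9, PDGFRB at 4.54 and POSTN at 7.07. VIM, the vimentin gene, picked out after its values were seen, was at 884 CPM in NTC and 857 in KD2 (adjusted p = 0.8268). Of the epithelial genes 5 of 13 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 7.80e-05, and adjusted p = 0.0453 with an estimated correlation). DSP rose to 171 CPM and CLDN4 to 25.3, whereas the keratin gene KRT7, again picked out after its values were seen, fell (-2.74).

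**Figure D2:**
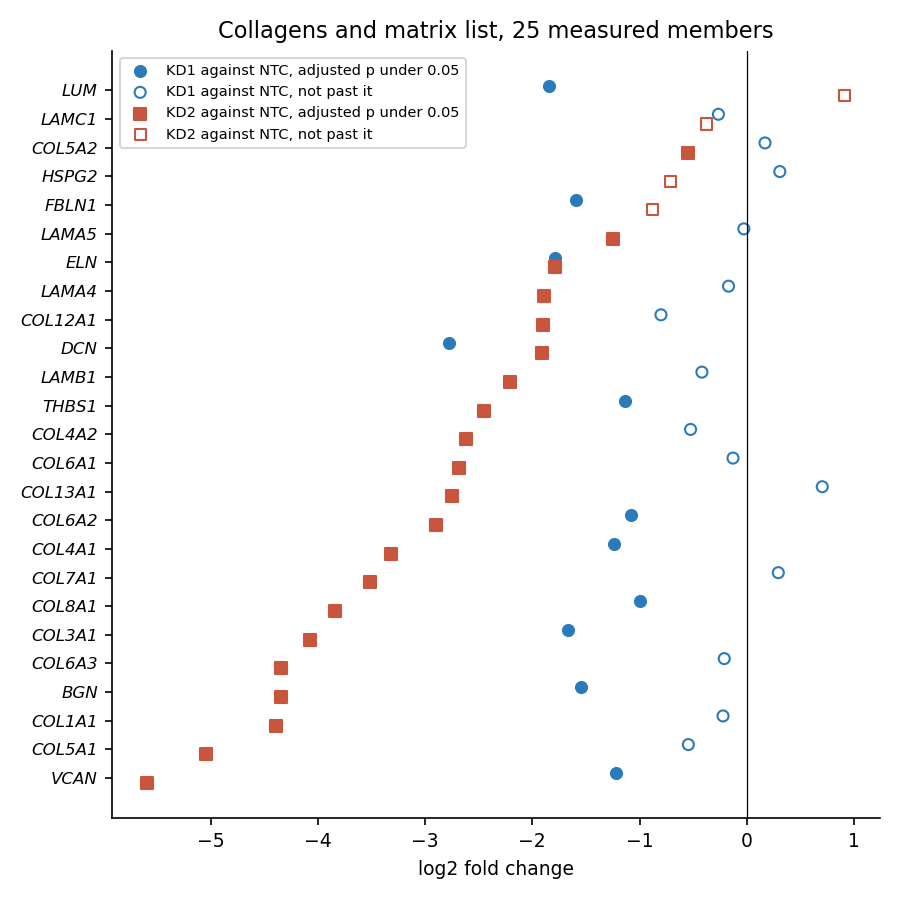
Log2 fold changes, on the log2(CPM + 1) scale, of the 25 measured members of the collagens and matrix list in KD1 (circles) and KD2 (squares) spheroids against NTC, filled where the limma adjusted p was under 0.05. In KD1 11 members fell and in KD2 21, with VCAN lowest at -5.59.

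Lower in KD2 were also interferon-stimulated genes, 14 of 26 with 0 higher (17 adjusted over the list alone; adjusted p = 9.84e-07, and adjusted p = 0.1026 with an estimated correlation). IFI44L was at 95.4 CPM in NTC and 12.4 in KD2. Of the antigen presentation genes 8 of 18 fell and 0 rose (9 adjusted over the list alone; adjusted p = 1.22e-04, and adjusted p = 0.2910 with an estimated correlation). B2M fell from 3963 to 1883 CPM and the peptidase gene ERAP2 from 265 to 102. HLA-B, which shares sequence with other class I genes, fell from 697 to 158 CPM. Mitochondrially encoded genes fell at 9 of 15, and 0 rose (11 fell adjusted over the list alone; adjusted p = 5.01e-05, and adjusted p = 0.2454 with an estimated correlation). MT-CO1 was at 4575 CPM in NTC and 2333 in KD2. Their share of all reads was 1.31% to 1.36% in NTC, 0.786% to 0.869% in KD1 and 0.702% to 0.965% in KD2. Of the integrins and focal adhesion list 10 of 23 fell and 2 rose (10 and 3 adjusted over the list alone; adjusted p = 0.0090, and adjusted p = 0.1172 with an estimated correlation). ITGA1, ITGA3 and ITGB3 fell to 59.5, 25.7 and 40.8 CPM from 193, 102 and 108, and ITGA6, which pairs in laminin receptors, rose to 564 from 238. Of the WNT pathway list 7 of 19 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0410, and adjusted p = 0.2365 with an estimated correlation). WNT5A, a secreted ligand gene, was at 279 and 47.6 CPM. The receptor gene FZD7 was higher, at 17.6 and 37.7. The integrins and focal adhesion list, with 4 rises and 1 fall in KD1 (6 and 4 adjusted over the list alone), was not called there (adjusted p = 0.0759), except without NTC replicate 1 (adjusted p = 0.0449). The WNT call ended without NTC replicate 1 (adjusted p = 0.0626).

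Genes of cholesterol synthesis and uptake rose in KD2 at 10 of 24, and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 5.01e-05, and adjusted p = 0.2365 with an estimated correlation). HMGCS1, an early enzyme gene of the pathway, was at 390 CPM in NTC and 557 in KD2, and MSMO1 at 391 and 612. Of the G2 and mitosis genes 11 of 25 rose and 0 fell (16 adjusted over the list alone; adjusted p = 1.53e-07, and adjusted p = 0.2316 with an estimated correlation). BUB1 was at 58.7 and 134 CPM and CCNB1 at 91.9 and 188. In the list of MYC targets and ribosome biogenesis 8 of 24 rose and 0 fell (8 adjusted over the list alone; adjusted p = 7.83e-04, and adjusted p = 0.4542 with an estimated correlation). MYC itself rose from 176 to 295 CPM and the polymerase subunit gene POLR1B from 66.3 to 103.

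Genes called with both knockdowns included CALB1, which encodes the calcium-binding protein calbindin, and CES1, a carboxylesterase gene. CALB1 (ENSG00000104327, chromosome 8, 90058608 to 90095475) rose from 0.857 ± 0.239 CPM to 23.9 ± 6.29 in KD1 and 138 ± 26.2 in KD2, and CES1 (ENSG00000198848, chromosome 16, 55802851 to 55833337) fell from 40.2 ± 2.94 to 0.817 ± 0.584 and 0.616 ± 0.514 (SD, n = 3 each). Altogether 150 genes rose and 300 fell with both, where independent lists would share 20.5 and 46.7. In opposite directions 31 were called (19 up in KD1 and down in KD2, 12 the reverse), against 62 for independent lists. Both comparisons use the same NTC libraries. In 100 simulations of unchanged groups with shared controls the shared calls averaged 0.05 and reached 2. As no gene changed in them, few calls could arise at all. They therefore do not gauge how far shared controls raise the overlap of real calls. The covariance of the fold changes across genes, which are not independent replicates, was 0.254 against 0.0764 simulated, a difference of 0.178, while the correlation was 0.511 against 0.500. The share of genes with the same sign was 63.5%, below the 66.6% simulated. With 3 controls no split leaves 2 libraries in each part, so some of the excess may come from the shared controls. Without NTC replicate 1, 2 or 3 the shared calls were 263, 244 and 250, without KD1 replicate 2 they were 292, without KD2 replicate 3 they were 608, and tested against a 1.5-fold change 96.

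The 12 rises with the largest smaller fold change were CALB1, FAM133A, SEPTIN14, PLAT, TMCC3, RHOXF2B, SOHLH2, GCNT3, TNFRSF9, CLDN4, PLXDC2 and TNS4. FAM133A went from 18.7 ± 1.98 CPM to 149 ± 4.96 and 148 ± 8.59 (SD, n = 3 each), the costimulatory receptor gene TNFRSF9 from 0.598 to 8.41 and 16, and SOHLH2, a germ-cell transcription factor gene, from 0.555 to 8.85 and 19.4. TMCC3 was near the floor in NTC (0.0668 CPM) and at 9.99 and 7.38 in KD1 and KD2. Reads of RHOXF2B cannot be told from its near-identical copy RHOXF2, those of SOHLH2 overlap a readthrough transcript and those of GCNT3 overlap GTF2A2 on the opposite strand, so these are uncertain. The 12 largest falls were CES1, SUCNR1, DCLK1, MEF2C, HS6ST3, KCNK2, FMO2, ROS1, DPT, DGKI, CASC19 and SEMA3A. MEF2C, which encodes a transcription factor, went from 93.7 ± 3.81 CPM to 7.08 ± 3.23 and 2.86 ± 0.579, the receptor kinase gene ROS1 from 67.2 ± 8.82 to 7.11 ± 1.57 and 1.58 ± 1.26, and SEMA3A, a secreted guidance factor gene, from 81.1 ± 4.90 to 9.24 ± 1.86 and 11 ± 3.82 (SD, n = 3 each). SUCNR1, the succinate receptor gene, was at 32.0, 0.978 and 1.16 CPM and the kinase gene DCLK1 at 38.5, 1.06 and 1.89. The long non-coding RNA CASC19 (288, 38.6 and 11.9 CPM) overlaps PCAT1 and PRNCR1 on the opposite strand and is uncertain.

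**Figure D3:**
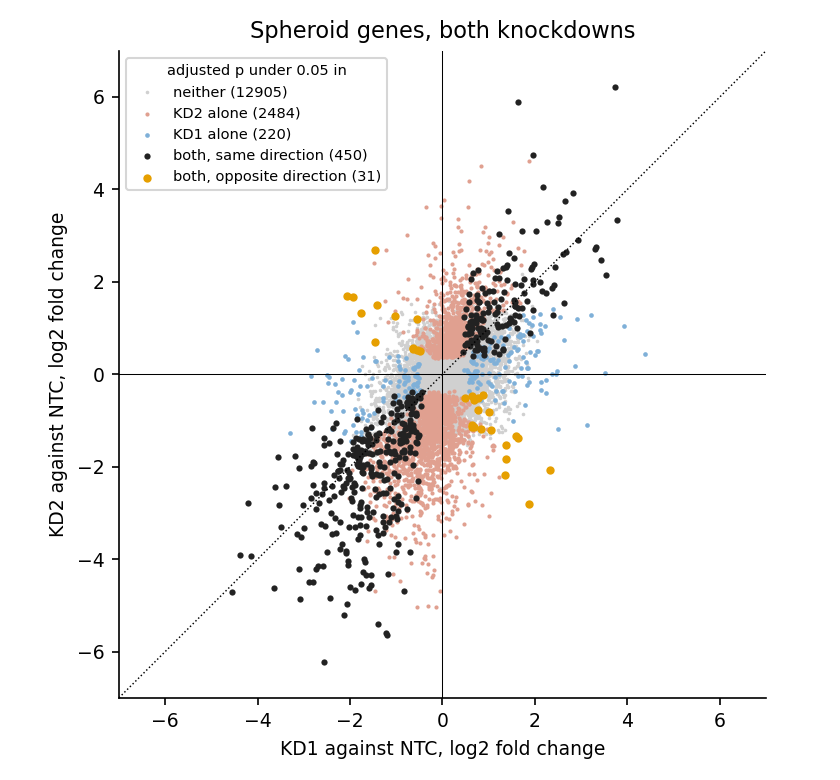
Log2 fold change against NTC, on the log2(CPM + 1) scale, in KD1 (x axis) and KD2 (y axis) spheroids, 1 point per tested gene, with the dotted line at equal change. Called in both the same way were 450 genes (black), in opposite ways 31 (orange), in KD2 alone 2484 and in KD1 alone 220.

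Some of the genes with the largest differences between KD2 and KD1 moved one way in KD1 and the other in KD2, and some the same way in both. IL7R was at 254 ± 33.9 CPM in KD1 and 7.52 ± 1.19 in KD2 (SD, n = 3 each; log2 difference -4.90, adjusted p = 4.90e-12), and ADAMTS12, a matrix protease gene, at 294 ± 29.5 and 10.9 ± 1.81 (-4.63). HPGD and PTGS1, both of prostaglandin metabolism, were higher in KD1 (107 and 277 CPM) and lower in KD2 (3.27 and 12.3) than in NTC (28.3 and 53.7). SPP1, the osteopontin gene, and NPTX2, a pentraxin gene, went the other way, at 20.4 and 21.1 CPM in NTC, 7.23 and 4.32 in KD1 and 137 and 70.7 in KD2, each past the threshold in all 3 contrasts. The amino acid transporter gene SLC7A8 rose with both, from 0.434 CPM in NTC to 3.43 in KD1 and 82.6 in KD2, and VCAN and PTGFR fell with both. LIX1 was listed at 0 in the 3 NTC libraries and was at 12.7 ± 2.46 CPM in KD2. In all, 873 genes were higher and 1530 lower in KD2 than in KD1 (4519 at an unadjusted p under 0.05), and libraries did not overlap for 31.3% of genes. The median of all genes was -0.13 and 0.03 with quantile normalization, under which 1144 were higher and 1243 lower, and a test against a 1.5-fold change called 510. Without KD2 replicate 3 the count was 2349. Also among the 8 largest each way were SLC1A6, MFAP3L, GPM6A and ST8SIA6 (higher) and MMP2, COL5A1, PTGFR and VCAN (lower).

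Camera called 13 of 36 lists between KD2 and KD1, 5 up and 8 down. The calls of 3 held with an estimated correlation. In the collagens and matrix list 19 of 25 were lower and 1 higher (20 and 2 adjusted over the list alone; adjusted p = 6.47e-18, then 0.0253). Of the mesenchymal genes 17 of 24 were lower and 0 higher (20 adjusted over the list alone; adjusted p = 4.08e-14, then 0.0131). Integrins and focal adhesion genes were lower at 14 of 23 and higher at 2 (18 and 2 adjusted over the list alone; adjusted p = 2.24e-05, then 0.0253). Interferon-stimulated genes were lower at 13 of 26 (14 adjusted over the list alone; adjusted p = 1.20e-06, and adjusted p = 0.0810 with an estimated correlation). Antigen presentation genes were lower at 7 of 18 (10 adjusted over the list alone; adjusted p = 5.87e-05, and adjusted p = 0.3062 with an estimated correlation). WNT pathway genes were lower at 8 of 19 (11 adjusted over the list alone; adjusted p = 2.27e-04, and adjusted p = 0.0567 with an estimated correlation). Matrix proteases and inhibitors were lower at 8 of 20 and higher at 1 (10 and 2 adjusted over the list alone; adjusted p = 2.86e-04, and adjusted p = 0.1324 with an estimated correlation).

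Higher in KD2 than in KD1 were cholesterol genes, 8 of 24 (8 adjusted over the list alone; adjusted p = 9.18e-06, and adjusted p = 0.1725 with an estimated correlation). MYC targets and ribosome biogenesis genes were higher at 6 of 24 (6 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.4731 with an estimated correlation). G2 and mitosis genes were higher at 5 of 25 and lower at 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.4731 with an estimated correlation). Epithelial genes were higher at 4 of 13 and lower at 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0362, and adjusted p = 0.1725 with an estimated correlation). Hypoxia genes were higher at 7 of 23 and lower at 6 (7 and 6 adjusted over the list alone; adjusted p = 0.05, just under the threshold before rounding, and adjusted p = 0.4364 with an estimated correlation). Without KD2 replicate 3 camera also called glycolysis, fatty acid synthesis and desaturation and the cytosolic ribosomal proteins higher in KD2 than in KD1 (adjusted p = 0.0039, 0.0068 and 0.0093). HMGCS1, at 277 CPM in KD1 and 557 in KD2, and ERO1A, a hypoxia-list oxidase gene, at 388 and 732, were among the higher genes. The epithelial call ended without KD1 replicate 3, KD2 replicate 1 or KD2 replicate 2 (adjusted p = 0.0723, 0.0720 and 0.0631), and the hypoxia call without NTC replicate 1 or 2, KD1 replicate 1 or KD2 replicate 2 or 3 (adjusted p = 0.0506, 0.0508, 0.1684, 0.0969 and 0.0581). The hypoxia call also ended with quantile normalization (adjusted p = 0.1657) and with the protein-coding total (adjusted p = 0.0531).

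SRF and MRTF targets, genes of the actin cytoskeleton, fell at 7 of 20 in KD2 and 1 rose, against 1 fall in KD1 (7 and 1, then 1, adjusted over the list alone; adjusted p = 0.0041 in KD2, and adjusted p = 0.3830 with an estimated correlation; adjusted p = 0.7968 in KD1). CALD1 was at 578, 364 and 260 CPM, and FLNA, the filamin gene, at 169, 222 and 67.0 CPM (adjusted p = 0.3736 in KD1). Between KD2 and KD1 10 of these 20 were lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 3.51e-04, and adjusted p = 0.3062 with an estimated correlation). Of the YAP and TEAD targets, 1 of 24 rose and 1 fell in KD1 and 2 rose and 7 fell in KD2 (2 and 4, then 2 and 8, adjusted over the list alone; adjusted p = 0.3248 and 0.3035). NT5E rose with both, from 19.6 CPM to 74.6 and 36.9, and TGFB2, a transforming growth factor gene, fell to 29.1 from 82.8 in KD1 and rose to 134 in KD2.

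**Figure D4:**
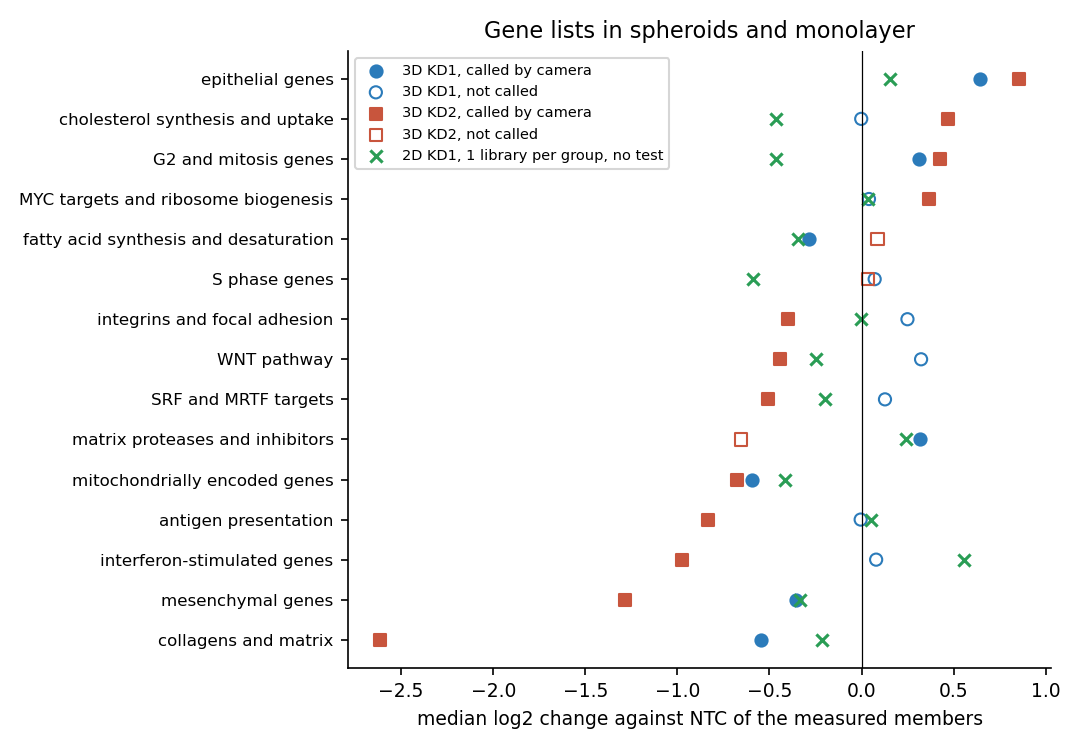
Median log2 change against NTC of the measured members of each list that camera called in KD1 or KD2 spheroids, and of the S phase list, for 3D KD1 (circles), 3D KD2 (squares) and 2D KD1 (crosses, 1 library per group, no test), filled where called. The collagens and matrix list had the lowest KD2 median, -2.61.

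Lineage lists were mixed. Of the basal and myoepithelial genes 2 of 15 rose and 3 fell in KD1 and 4 rose and 4 fell in KD2 (3 and 5, then 4 and 4, adjusted over the list alone; camera adjusted p = 0.3248 and 0.9642). TP63, a basal transcription factor gene, fell from 101 CPM to 44.7 and 10.6, and MME fell to 34.3 from 71.8 in KD1 and rose to 171 in KD2. Of the luminal genes 1 of 9 rose and 2 fell in KD1 and 0 rose and 4 fell in KD2 (2 and 2, then 3 and 4, adjusted over the list alone; adjusted p = 0.7968 and 0.5251). FOXA1, a luminal transcription factor gene, was at 43.2, 5.45 and 18.8 CPM. Of the breast stem-like genes 2 of 15 rose and 2 fell in KD1 and 3 rose and 3 fell in KD2 (4 and 2, then 5 and 5, adjusted over the list alone; adjusted p = 0.7792 and 0.8667). NOTCH3 was at 106, 43.1 and 17.2 CPM. Of 27 measured SWI/SNF subunits 0 passed in KD1, and in KD2 3 rose and 2 fell, SMARCA4 among the falls (2 and 0, then 3 and 3, adjusted over the list alone; adjusted p = 0.7792 and 0.9289). BICRAL and ARID1A rose in KD2, from 59.7 to 96.0 and from 59.5 to 88.5 CPM. Of the polycomb subunits 0 of 23 passed in KD1, and 2 rose and 5 fell in KD2 (0, then 2 and 5, adjusted over the list alone; adjusted p = 0.7968 and 0.8667). SUZ12 was higher in KD2, at 257 and 504 CPM. Of the TGF-beta response genes 0 of 20 rose and 2 fell in KD1 and 2 rose and 6 fell in KD2 (0 and 2, then 2 and 7, adjusted over the list alone; adjusted p = 0.0759 and 0.1028). Camera called that list in KD1 without NTC replicate 3 (adjusted p = 0.0379) and in KD2 without KD2 replicate 3 (adjusted p = 0.0473). For other cell types, 1 of 16 leukocyte markers was measured, so that list was not tested. It was PTPRC, at 106 CPM in NTC, 72.3 in KD1 (adjusted p = 0.2487) and 7.74 in KD2, where it fell. Of 12 endothelial markers 5 were measured, 0 passed in KD1, and 2 rose and 2 fell in KD2 (0, then 2 and 3, adjusted over the list alone; adjusted p = 0.8862 and 0.9289). ERG was at 1.94 and 11.8 CPM.

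Camera called none of the following lists of proliferation, stress and metabolism in KD1 or KD2. In KD1 0 members passed of the 25 S phase genes, the 14 replication-dependent histones, the 18 glycolysis genes, the 25 nuclear oxidative phosphorylation genes, the 20 AP-1 and immediate early genes and the 28 cytosolic ribosomal proteins, and adjusted over the list alone 1 glycolysis gene fell (adjusted p = 0.7968, 0.8862, 0.7333, 0.7968, 0.7968 and 0.0759). In KD2 the same lists had 0, 1, 5, 1, 2 and 2 rises and 0, 1, 2, 1, 3 and 4 falls (adjusted over the list alone 0, 1, 5, 1, 2 and 2 rises and 0, 1, 4, 0, 4 and 4 falls; adjusted p = 0.3035, 0.8667, 0.5930, 0.7795, 0.9289 and 0.9642). Leaving out 1 library made some of these calls: the ribosomal proteins in KD1 without KD1 replicate 1 or KD2 replicate 3 (adjusted p = 0.0242 and 0.0346) and glycolysis in KD2 without KD2 replicate 3 (adjusted p = 0.0473). DUSP6, a phosphatase gene of the MAP kinase pathway, fell in KD2 from 528 to 148 CPM, ALDOC, an aldolase gene, rose from 10.0 to 23.3 and CYCS, the cytochrome c gene, from 788 to 1303. Of the p53 targets 0 of 19 rose and 2 fell in KD1 and 1 rose and 4 fell in KD2 (1 and 2, then 1 and 4, adjusted over the list alone; adjusted p = 0.7792 and 0.1137). SESN1 was at 100, 55 and 39.2 CPM. Of the apoptosis regulators 1 of 18 rose and 0 fell in KD1 and 3 rose and 4 fell in KD2 (1 and 0, then 3 and 4, adjusted over the list alone; adjusted p = 0.7968 and 0.8667). The KD1 rise was that of BIRC3, to 216 CPM. Of the cytokines and NF-kB targets 1 of 17 rose and 3 fell in KD1 and 1 rose and 6 fell in KD2 (2 and 6, then 3 and 8, adjusted over the list alone; adjusted p = 0.0612 and 0.7749). IL1B was at 3.24 CPM in NTC and 0.287 in KD1. Of the unfolded protein and ATF4 response genes 0 of 19 rose and 1 fell in KD1 and 3 rose and 4 fell in KD2 (2 and 1, then 3 and 4, adjusted over the list alone; adjusted p = 0.7968 and 0.8824). ASNS, the asparagine synthetase gene, was higher in KD2, at 5.35 and 27.1 CPM. Of the hypoxia genes 2 of 23 rose and 1 fell in KD1 and 7 rose and 5 fell in KD2 (5 and 1, then 9 and 6, adjusted over the list alone; adjusted p = 0.7792 and 0.0734). LOX, the lysyl oxidase gene, fell with both, from 119 CPM to 47.3 and 29.5. Median, mean and test differed in sign for 6 lists in KD1, 11 in KD2 and 10 between KD2 and KD1, all of them not called.

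Reads of some genes named here may belong to a gene on the opposite strand, for example KRT8 at KRT18, COL4A2 at COL4A1, FSIP1 at THBS1, SRFBP1 at LOX, TTC6 at FOXA1, CYFIP2 and NIPAL4 at ADAM19 and WTAPP1 at MMP1. Others overlap antisense or unnamed transcripts. ITGA1 shares its strand with PELO inside it.

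In 2D, the medians of the cell-cycle and cholesterol lists were lower in the single KD1 library than in the single NTC library and that of the interferon list higher, though few members passed the size rule. The S phase list had a median log2 ratio of -0.59 (percentile 0.0 of random lists) over 25 members, the G2 and mitosis list -0.46 (0.0), the replication-dependent histones -0.56 (0.2), cholesterol synthesis and uptake -0.47 (0.1) and the mitochondrially encoded genes -0.42 (0.3), where the random lists centred between -0.15 and -0.13. Interferon-stimulated genes had a median of 0.56 (100.0, random lists -0.11), matrix proteases and inhibitors 0.24 (99.1), basal and myoepithelial genes 0.22 (98.3) and p53 targets 0.17 (97.7). Past the size rule and lower were 3 of 25 S phase genes, 2 of 25 G2 and mitosis genes, 0 of 14 histones and 3 of 22 cholesterol genes. Of the 15 mitochondrially encoded genes 1 was higher and 1 lower. Higher were 2 of 19 interferon-stimulated genes, 1 of 17 proteases and inhibitors, 2 of 12 basal genes and 0 of 17 p53 targets. Within the interferon list IFI44L was nonetheless lower in KD1 (6.11 and 2.59 CPM), while ISG15, picked out after its values were seen, was at 2.86 and 12.7. RRM2, a ribonucleotide reductase gene, was at 136 CPM in NTC and 90.2 in KD1, CDC6 at 48.5 and 27.7, HMGCS1 at 281 and 129, and MSMO1 at 225 and 106. Mesenchymal genes had a median of -0.33 (2.8), epithelial genes 0.15 (88.7) and collagens and matrix -0.22 (19.2). The percentiles describe these libraries. Scaling to the protein-coding total left each of the first 9 on its side of the random lists. That scaling shifts lists and random lists nearly alike, so it could hardly do otherwise and is no check of the percentiles. With it the S phase median was -0.45 and the G2 and mitosis median -0.32.

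In all, 328 genes were at least 2-fold higher and 387 at least 2-fold lower in 2D KD1, of 9218 with at least 5 CPM. Small nucleolar RNA made up 112 of the higher and 1 of the lower genes, protein-coding genes 184 and 295, and long non-coding RNA 9 and 69. The median log2 ratio was -0.13, and 0.02 when scaled to the protein-coding total, under which 447 were higher and 250 lower. GFRA1, a GDNF receptor gene, was at 72.5 CPM in NTC and 6.52 in KD1, SULT1B1, a sulfotransferase gene, at 149 and 15.5, and the transcription factor gene PROX1 at 10.2 and 1.30. NPTX2 (17.5 and 2.63 CPM), MCAM (28.8 and 4.96), CRYGS (13.1 and 2.11) and TGFB2-OT1 (32.8 and 5.75) were also among the 8 lowest ratios of genes with at least 10 CPM. Most small RNA families and unnamed transcripts were left out of the ranking, but not small Cajal body RNA (scaRNA). Among genes with at least 10 CPM in the higher library, the 8 highest included SCARNA1, itself a scaRNA (1.22 and 15.1 CPM), CHTF8 (1.39 and 14.9), TRAPPC6B (8.84 and 44.0) and MGST3 (4.58 and 23.0). The rest were PKP2, a desmosomal gene (2.10 and 12), TCTA (3.70 and 18.3), HIF1AN (28.4 and 115) and LIN28B, which encodes an inhibitor of let-7 processing (2.21 and 11.7). SCARNA1 lies inside PPP1R8, TGFB2-OT1 inside TGFB2, CRYGS overlaps TBCCD1, and CHTF8, TCTA, HIF1AN and MCAM overlap genes on the opposite strand, so their values are uncertain.

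Genes that fell in KD1 spheroids were lower in the KD1 monolayer more often than all measured genes were. Those that rose in spheroids were higher there more often than all measured genes were. Of 263 falls measured at 5 CPM or more in 2D, 205 had a ratio below 0 (77.9%; median -0.43, percentile 0.0, random lists -0.13), where 62.2% of all such genes lay below 0. Of 207 rises, 109 had a ratio above 0 (52.7%; median 0.03, percentile 100.0, random lists -0.13), where 37.8% of all such genes lay above 0. Past the 2D size rule were 51 of the falls the same way and 5 the other way, and of the rises 14 and 1. Across 9144 genes the Spearman correlation of the KD1 spheroid change and the 2D ratio was 0.141. CASC19 was at 116 CPM in 2D NTC and 33.9 in 2D KD1, ROS1 at 46.5 and 22.0, and VCAN at 35.2 and 14.5, while COL3A1 was low in both (1.57 and 2.43). FAM133A was at 30.4 and 59.2 CPM and BIRC3 at 541 and 1079. With the protein-coding total the shares were 69.2% and 64.7%, with medians of -0.29 and 0.18, and the difference between culture conditions was not tested.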

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

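The limits used in this part were chosen after the data had been examined. They picked out named genes called in the KD1 spheroids with no overlap of libraries whose 2D ratio went the other way by at least 2-fold and beyond counting error, and 3 met them. Other named genes went the other way in 2D by less, such as TNFRSF9 (2.52 in KD1 spheroids and -0.64 in 2D) and COL3A1 (-1.67 and 0.42). TNS4, which encodes a focal adhesion protein, rose in spheroids (log2 fold change 2.44 in KD1 and 2.31 in KD2) and had a log2 ratio of -1.039 in 2D (3.06 and 0.973 CPM). MEF2C fell in spheroids (-3.65 and -4.63) and had a ratio of 1.244 in 2D, where it was at 0.038 and 1.459 CPM, about 1 and 45 reads. SEMA3A fell in spheroids (-3.02 and -2.82) and had a ratio of 1.592 in 2D (0.267 and 2.822 CPM, about 7 and 87 reads). All 3 were low in the monolayer, which had 1 library per group, and the difference between the culture conditions was not tested. No biological explanation was tested.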

How the results depend on the processing

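The alternatives were chosen before the data were examined, except scaling to the protein-coding total, which was chosen after seeing the data. With whole counts not recovered, alternatives that need counts (other size factors, a second count tool, count weighting and thinning to equal depth) were not run. A gene under 0.0574 to 0.101 CPM in a spheroid library has fewer than 3 reads, so a fall below that level has no measured size. Tested against a 1.5-fold change, the counts were 149 in KD1, 882 in KD2, 510 between KD2 and KD1 and 96 shared, a stricter hypothesis by construction, and ARHGAP29 in KD1 (-0.96) did not pass (adjusted p = 0.4685, range over alternatives 7.11e-05 to 0.4685). Leaving out 1 library at a time gave 369 to 1076 genes in KD1 and 244 to 608 shared genes, and 2033 to 3043 in KD2 and 1633 to 2349 between KD2 and KD1. Fewer libraries give less power by construction. The rise to 1076 without KD2 replicate 3 can act only through the shared spread and the filter, and the cause was not tested. Called lists went from 7, 12 and 13 to 0, 3 and 3 with an estimated correlation, where the cause was not tested. The estimate was under the preset 0.01 for the epithelial list (-0.011) and the integrins and focal adhesion list (-0.031). A higher correlation thus cannot account for their lost calls in KD1 and KD2, respectively. For other lists, such as the mitochondrially encoded genes (0.241), the estimate was above it. With fry, which tests another hypothesis, they were 8, 20 and 15. Fry ended 7 camera calls. They were G2 and mitosis and fatty acid synthesis in KD1 (fry adjusted p = 0.0961 and 0.2220) and MYC targets in KD2 (0.1253). Between KD2 and KD1 they were the epithelial, G2 and mitosis, hypoxia and MYC target lists (0.1282, 0.1836, 0.1544 and 0.1849). Fry added 16 calls, such as YAP and TEAD targets, luminal genes and p53 targets in KD2 (0.0070, 0.0111 and 0.0056). The breast stem-like list turned its direction with fry (adjusted p = 0.0157 in KD2 and 0.0056 between KD2 and KD1), and the cause was not tested. The other alternatives left the counts within 1.5 times, with quantile normalization at 788, 3066, 2387 and 497. A replicate block gave 657, 2867, 2312 and 420 and changed no call on a list. Same-number libraries correlated at -0.089 to 0.145 after group means were removed and other-number libraries at -0.117 to 0.093, and 2 of 9 libraries were closest to their own number, so they were not treated as pairs. SMARCA4 in KD1 passed under none (adjusted p = 0.2706 to 1.0000) and in KD2 under all (2.00e-04 to 0.0261). In 2D a minimum of 1 CPM gave 1271 genes, 1.5-fold 2139, 4-fold 71 and a pseudocount of 5 298, by construction, and the protein-coding total 697. For KD1 genes in 2D that total moved the share of rises to 64.7% with a median of 0.181 and of falls to 69.2% with a median of -0.287, because it lifts every ratio. Genes that fell with both knockdowns had a 2D median of -0.55, and the cause was not tested. Of the named genes' alternative values 6352 kept their side of the threshold, 105 gained it, 358 lost it and 0 turned direction while past it in either fit. RHOA in KD1, never past it, went from -0.06 to 0.04 with quantile normalization and 0.01 without NTC replicate 2.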

Other observations

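Of the genes with the largest 2D ratios, most did not pass the threshold in KD1 spheroids. Some did, and moved the same way as in 2D. LIN28B, which keeps let-7 microRNA low, rose from 8.32 ± 2.68 CPM in NTC to 24.2 ± 7.75 in KD1 and 104 ± 14.4 in KD2 (SD, n = 3 each; log2 fold changes 1.42 and 3.52, limma adjusted p = 0.0068 and 1.55e-07). GFRA1 fell from 19.1 ± 3.60 CPM to 3.78 ± 2.92 and 0.459 ± 0.213 (-2.22 and -3.78, limma adjusted p = 0.0090 and 1.72e-05). SULT1B1 fell from 29.6 ± 9.57 CPM to 5.39 ± 4.23 and 5.23 ± 2.91 (-2.57 and -2.36, limma adjusted p = 0.0162 and 0.0082). PROX1, a lymphatic and neural transcription factor gene, was at 53.7, 28.5 and 1.79 CPM in NTC, KD1 and KD2. It fell in KD2 (-4.48, limma adjusted p = 4.20e-07) and did not pass in KD1 (-0.91, limma adjusted p = 0.2668), and KD2 differed from KD1 (-3.57, limma adjusted p = 8.76e-06). Others went against their 2D ratio in KD2. MGST3, a glutathione transferase gene, had a ratio of 2.10 in 2D and fell in KD2 (-1.58, limma adjusted p = 7.37e-04). CHTF8 had a ratio of 2.74 and fell in KD2 (-1.08, limma adjusted p = 0.0157). NPTX2 had a ratio of -2.35, fell in KD1 spheroids as in 2D (-2.07, limma adjusted p = 2.11e-04) and rose in KD2 (1.70, limma adjusted p = 2.93e-04).

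The weighing below rests on predictions written before its tests were run, except both tests of the cell-cycle lists and the test with held-out KD1 libraries, which were written after the result was seen. More genes changed in KD2 than in KD1, at 2965 and 701. A larger fall of SMARCA4 in KD2 predicts that most KD1 changes move further in KD2, and 42.7% did, but that share is biased low because the same KD1 values selected the genes. With 1 KD1 library held out of the selection and compared with KD2 instead, it was 49.6% on average (47.7% to 51.9% over the 3 libraries). About as many of these genes lay less far in KD2 as lay further. By the limits set for this test, these shares neither met the prediction nor counted against it. Genes that already lay near the floor in KD1 could hardly fall further, which can lower the share. The test therefore does not decide why more genes changed in KD2. The ratio of the counts was 4.23, and 2.77 without KD2 replicate 3, where the KD1 count rose to 1076. Its lowest value under the other scalings was 3.89. Leaving out that library thus narrowed the gap, and neither that nor scaling closed it. The larger fall of SMARCA4 might remain, as might a response that starts only at lower SMARCA4 or an effect particular to 1 hairpin. Neither of the latter was tested.

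The medians of the cell-cycle lists were lower in the KD1 monolayer and not in the KD1 spheroids, though only 3 and 2 of 25 genes passed the 2D size rule. Scaling to the protein-coding total left the higher of both list medians at -0.315, so scaling alone is unlikely to explain it. With 1 monolayer library per group, the state of a single culture cannot be told apart from an effect of the knockdown.

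Of 15 mitochondrially encoded genes 7 fell in KD1 and 9 in KD2. The list call was lost in both with an estimated correlation (adjusted p = 0.1181 and 0.2454). A fall shared by all abundant genes is unlikely, since the list medians lay at or under percentile 0.05 of random lists matched on expression, and no other scaling raised a median above -0.56. The values are consistent with lower RNA of these genes in both knockdowns, while a shared property of the 3 NTC libraries could produce the same result and was not tested.

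Regrouping the libraries tested whether any split gives as many calls. With 3 libraries per group there are only 10 splits, too few for a share under 0.05. The real grouping was the only 1 of 10 to reach its count in KD1 (701, highest other split 1), in KD2 (2965, highest other 0) and between KD2 and KD1 (2403, highest other 0). Every other split mixes libraries of both groups, so any difference between the groups widens the spread within its parts and lowers its count. The low counts therefore do not gauge how many calls arise by chance. Of 100 splits of the 9 libraries, the real grouping counted among them, 2 shared at least 450 genes, and the real grouping was 1 of these. The other gave 1276, and in it the 3 KD2 libraries served as controls against mixtures of NTC and KD1. Such a split again contrasts KD2 with the rest, so it may count the difference of KD2 rather than chance.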
